A study of Rattus norvegicus with 17 samples.

How the data were processed

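The series holds bulk RNA sequencing of lung parenchyma from Wistar rats (strain RjHan:WI) in 17 libraries. Per the labels' protocols, RNA was extracted with a column kit (RNeasy mini plus, Qiagen) and made into TruSeq mRNA libraries. The labels put 6 libraries in a control group given NaCl, 5 in a group given bleomycin at 1 mg per kg, and 6 in a group given bleomycin at 1 mg per kg and BI1015550 at 2.5 mg per kg. Libraries are named here by their group and the number in their title. The numbers differ between groups, so they pair no libraries, and the labels give no batch, sex or time point. They run on from control through bleomycin to treated libraries, so an effect of any order that follows them could not be told apart from group. In the bleomycin group they go from 9 to 11, and the labels used here give no reason for the gap. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

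The authors deposited 1 table of whole-number read counts per gene for the 17 libraries, and each column name matched 1 sample label. Per the submitters' processing notes, the tools included bcl2fastq 2.20.0.422, STAR 2.5.2 and 2.5.2b, featureCounts 1.5.1, RSEM 1.3.0 and FastQC 0.11.5. The same notes list the rat build Rnor_6.0 and the human build names hg38 and GRCh38, with no role for any of them. Which tool made the deposited counts, the annotation release, the strand setting and any filter are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies may therefore have been shared or dropped, and values of single genes carry that limit.

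The table identifies 32753 genes by Ensembl rat gene IDs and does not pair the IDs with gene names. The rat gene table used as a reference (assembly GRCr8) lists no Ensembl IDs, so it could not be used to look these IDs up. Gene names, functions and positions are therefore not given. The tests of gene lists, the values of phosphodiesterase genes and the genes that were to be named by symbol, all fixed before the data were examined, were not run. The rule for named genes took genes with an adjusted p below 0.05, a mean of at least 5 CPM (counts scaled by library size) over all libraries and group ranges that did not overlap, ordered by log2 fold change. Its requirement of a gene symbol could not be applied. The first 2 genes in each direction for bleomycin against control are named by ID.

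Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of the 23083 genes with a count in any library, 15000 passed the edgeR expression filter (filterByExpr, by group), and these hold 99.927% of all counts. Libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with the 3 groups was fitted to all 17 libraries at once, so that the groups share 1 estimate of the spread, and each pair of groups was compared by the quasi-likelihood F test. P-values were adjusted over the tested genes by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p below 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM values for principal components and scores use a prior count of 2. The common dispersion was 0.0397, a biological coefficient of variation of 19.9%.

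Bleomycin against control and treated against bleomycin share the bleomycin libraries, which gives their fold changes a negative relation without any effect of the compound. The relation is therefore given beside 20 simulated data sets in which the treated group equals the bleomycin group, and beside 20 splits in which each comparison used different bleomycin libraries. A bleomycin score was also computed for every library, as the mean log2 CPM of up to 200 genes called higher with bleomycin minus that of up to 200 called lower. No control or bleomycin library was scored on genes that it had helped to choose. Treated libraries were scored with each signature used for a bleomycin library and averaged. Scores were compared by two-sided exact permutation tests, whose smallest possible p is 0.00216 for 5 against 6 libraries. The size of the change left in treated lungs was measured on genes chosen with one part of the control and bleomycin libraries and measured in the other part, over 40 random splits, leaving out bins of under 20 genes.

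The test was run on simulated counts with 200 genes changed among the measured genes. At 2-fold it recovered 78.5% of them for bleomycin against control, 81.5% for treated against bleomycin and 74% for treated against control. At 1.5-fold it recovered 43%, 46.5% and 46%, and at 4-fold 97%, 94% and 96%. Many more genes were called in the data than were changed here, which makes the adjustment of p less strict in the data. These shares may therefore understate the recovery there. Of the genes called in these simulations, 2.105% to 7.5% had not been changed, and for treated against control the share was 7.071%, 7.5% and 6.341% at the 3 sizes, above the rate that the threshold of 0.05 aims at. The bleomycin score was tested on 8 simulated data sets with no effect of the compound. Its difference there was at most 0.0523 in size, and no data set gave a p below 0.05. Genes were drawn independently in all of these simulations, so they lack the spread between libraries that genes share. The 8 data sets are also too few to measure an error rate of the score. Within groups, 40 pairs of libraries were compared by chi-square per degree of freedom over genes with at least 10 counts, which ran from 10.98 to 83.2, so no pair looked like 1 library deposited again.

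Alternatives chosen before the data were examined were DESeq2 size factors or upper quartile scaling in edgeR, DESeq2 1.42.0 (Wald test), limma 3.58.1 (voom with quality weights), other filters on low counts, a stricter adjusted p, a fold threshold, fits of only the 2 groups compared, 1 surrogate variable (sva 3.50.0), other score sizes, and leaving out each library in turn. Added after seeing the data were thinning every library to the smallest total, leaving out 3 libraries high on an axis of variation within groups, leaving out treated libraries 13 and 17, and the geometric measures of the treated change.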

Results

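RNA was sequenced from lung parenchyma of rats in 3 groups. Bleomycin is a cytotoxic antibiotic used to injure the lungs of rodents and produce fibrosis. BI1015550 is named in the series title as an inhibitor of PDE4B, a phosphodiesterase that degrades cyclic AMP, and the model is described there as therapeutic. There were 6 control libraries, 5 bleomycin libraries and 6 libraries from lungs given bleomycin and BI1015550, called treated below. The total count per library was 16867155 ± 866040 in controls (SD, n = 6, 15919392 to 18462105), 15838211 ± 376603 with bleomycin (SD, n = 5, 15207791 to 16192209) and 15040122 ± 494616 in treated lungs (SD, n = 6, 14609389 to 15889091). Treated totals differed from controls by -1827033 counts (exact permutation test, two-sided, p = 0.00216, adjusted p = 0.00972 over 9 tests of library properties) and from bleomycin by -798089 counts (exact permutation test, p = 0.026, adjusted p = 0.0468). Between 18461 and 18656 genes had a count in an average library of each group.

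The 10 most abundant genes of a library held 8.72% ± 0.518 of the counts with bleomycin (SD, n = 5), against 6.91% ± 0.707 in controls (SD, n = 6) and 6.76% ± 0.28 in treated lungs (SD, n = 6). The share was higher with bleomycin than in controls by 1.81 percentage points (exact permutation test, p = 0.00433, adjusted p = 0.013). In treated lungs it lay below bleomycin by a difference of -1.96 points (exact permutation test, p = 0.00216, adjusted p = 0.00972). Treated and control lungs differed by -0.155 points, less than the spread between libraries (exact permutation test, p = 0.643).

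The 3 groups separated on the first principal component of log2 CPM, which held 35.8% of the variance. Controls lay at -32.6 ± 4.37 (SD, n = 6), treated lungs at -3.93 ± 8.07 (SD, n = 6) and bleomycin lungs at 43.9 ± 17 (SD, n = 5), and the ranges of the groups did not overlap. On the second component, with 14.3% of the variance, treated lungs lay at -18.9 ± 13.5, while controls lay at 10.8 ± 17.1 and bleomycin lungs at 9.77 ± 18.4.

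**Figure D1:**
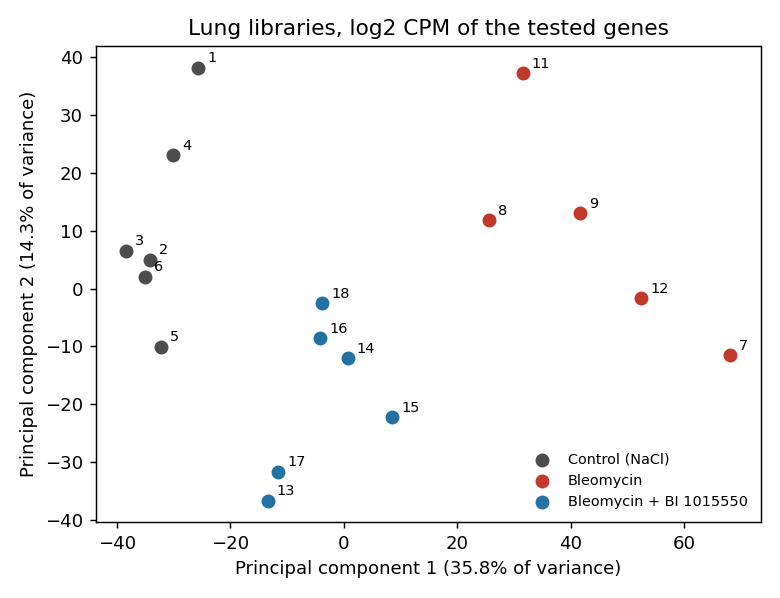
Each point is 1 lung library, placed by its first and second principal component of log2 CPM over the tested genes (axes in component units, with the share of variance), coloured by group and numbered as in the labels. Treated libraries run from -13.4 to 8.57 on the first component, between the controls (-38.4 to -25.7) and the bleomycin libraries (25.5 to 68.2).

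The first comparison asks what bleomycin changed. Bleomycin changed 5738 of the 15000 genes tested (38.3%), with 3032 higher and 2706 lower than in controls. Most changes were small, with a median log2 fold change of 0.583 among the genes that rose and -0.622 among those that fell, and a median SE of 0.143. At least 2-fold changes were found for 737 genes that rose and 623 that fell, and at least 4-fold changes for 200 and 87. The gene ENSRNOG00000011824 rose from 0.249 ± 0.163 CPM in controls to 33.6 ± 8.65 CPM with bleomycin, a log2 fold change of 7.05 (SE 0.362, edgeR adjusted p = 3.03e-09), or 133-fold.

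The gene ENSRNOG00000006151 had the largest rise that met the naming rule, with a log2 fold change of 7.49 (SE 1.6, edgeR adjusted p = 0.00157). Its mean went from 0.137 ± 0.118 CPM to 25.9 ± 45.5 CPM, and bleomycin library 7 alone reached 106 CPM while the others lay between 0.467 and 19. Without that library the log2 fold change was 5.33, and limma voom with quality weights gave 4.15 with an adjusted p of 0.0803. In the other direction, ENSRNOG00000019584 fell from 14.9 ± 11 CPM to 0.492 ± 0.193 CPM, a log2 fold change of -4.90 (SE 0.671, edgeR adjusted p = 4.03e-05), or -4.30 with limma voom. ENSRNOG00000032871 fell from 7.04 ± 2.91 CPM to 0.325 ± 0.123 CPM, a log2 fold change of -4.40 (SE 0.755, edgeR adjusted p = 0.000275).

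**Figure D2:**
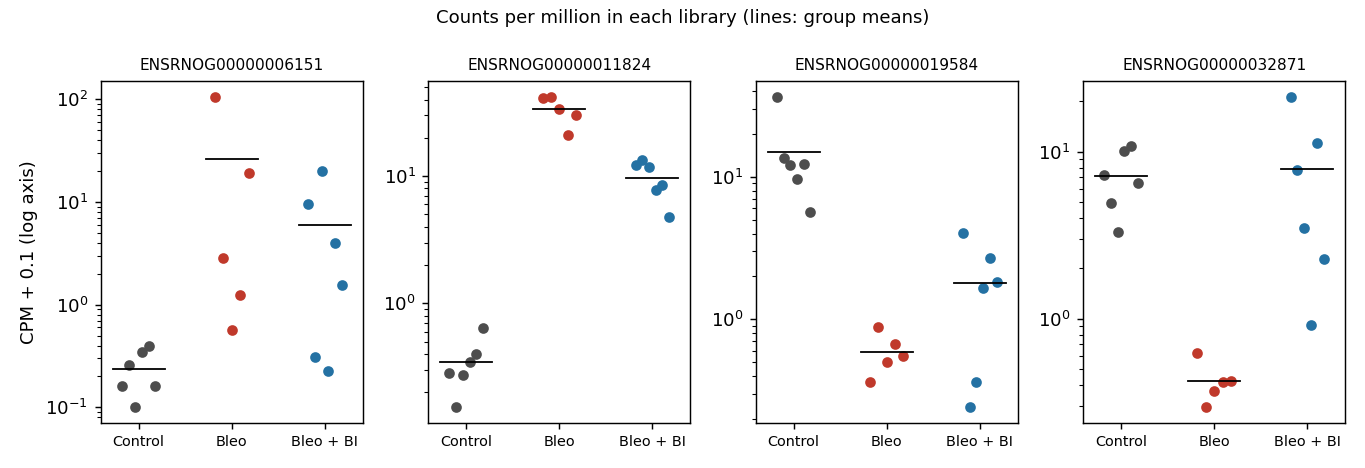
CPM with a small constant added (log axis) of 4 genes in each library of the control, bleomycin and treated groups; points are libraries and lines are group means. ENSRNOG00000011824 averaged 0.249, 33.6 and 9.63 CPM in the 3 groups, and ENSRNOG00000032871 averaged 7.04, 0.325 and 7.73 CPM.

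Among the genes changed by bleomycin, 24 that rose had a mean below 0.2 CPM in controls. Their median level was 0.107 CPM in controls, 2.17 CPM with bleomycin and 0.635 CPM in treated lungs. Of these 24 genes, 15 were lower in treated than in bleomycin lungs and 13 were still higher than in controls. The same libraries chose these genes and gave their levels. That choice alone draws control levels down and bleomycin levels up, and no held-out measure was made for these genes. Abundant genes were called more often than rare ones. Of the 2309 genes above 100 CPM 46.4% were called, against 26.6% of the 887 genes below 1 CPM, whose median SE was 0.37 against 0.105. CPM ranges of bleomycin and control libraries did not overlap for 2711 genes (18.1%), where chance gives 0.433%.

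The second comparison asks what the compound changed in lungs given bleomycin. Treated lungs differed from bleomycin lungs in 4163 genes (27.8%), with 1813 higher and 2350 lower. The median log2 fold change was 0.531 among genes that were higher and -0.504 among those that were lower, with a median SE of 0.132. At least 2-fold changes were found for 286 genes that were higher and 366 that were lower. ENSRNOG00000032871 was 23.2-fold higher than with bleomycin (log2 fold change 4.54, SE 0.755, edgeR adjusted p = 0.00107), at 7.73 ± 7.63 CPM. Its log2 fold change was 3.92 without treated library 13 (adjusted p = 0.00192), 3.40 without treated libraries 13 and 17 (0.00432) and 3.72 with limma voom (0.0309). ENSRNOG00000011824 was 3.49-fold lower (log2 fold change -1.80, SE 0.251, edgeR adjusted p = 0.000447), at 9.63 ± 3.28 CPM.

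The other two named genes did not pass the test in this comparison. ENSRNOG00000006151 averaged 5.84 ± 7.72 CPM in treated lungs, a log2 fold change of -2.15 against bleomycin (SE 1.07, edgeR adjusted p = 0.142). The log2 fold change was 0.0047 without bleomycin library 7, -0.32 with limma voom (adjusted p = 0.867) and -3.09 without treated library 15 (edgeR adjusted p = 0.0582). ENSRNOG00000019584 averaged 1.7 ± 1.43 CPM, a log2 fold change of 1.77 (SE 0.704, edgeR adjusted p = 0.0683). That gene passed the threshold with DESeq2 (adjusted p = 0.035), with 1 surrogate variable (0.0282), and without treated library 14 (0.0294) or 15 (0.0358). Its log2 fold change was 0.92 with limma voom (adjusted p = 0.511), 0.91 without treated libraries 13 and 17 (0.415) and 1.34 without treated library 13 (0.177).

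Of the 4163 genes that differed between treated and bleomycin lungs, 3142 (75.5%) had changed with bleomycin in the opposite direction. Another 6 (0.144%) had changed in the same direction, and 1015 (24.4%) had not been called with bleomycin. Among the 3032 genes that rose with bleomycin, 1838 (60.6%) were lower in treated than in bleomycin lungs, where independent lists would share 475. Among the 2706 that fell, 1304 (48.2%) were higher in treated lungs, where independent lists would share 327. Independent lists leave out the bleomycin libraries that both comparisons share. With different bleomycin libraries in each comparison, a median of 32.5% of the genes changed by bleomycin moved back (4.79% to 56.2% over 20 splits), from fits with fewer libraries in each part. Further movement in the direction of bleomycin was called for 5 genes that had risen and 1 that had fallen. The shared bleomycin libraries make such calls rarer. With different bleomycin libraries in each comparison, a median of 90.8% of the genes changed by bleomycin had a fold change of opposite sign (79.1% to 96.2%), called or not. Leaving out treated libraries 13 and 17 together lowered the 4163 genes to 1929 and the 3142 genes to 1684. Of the treated libraries, these lay nearest the controls on the first principal component (-13.39 and -11.57). Their removal also left fewer treated libraries, so lower counts had to follow, and how much rests on them stays open.

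Across genes, the log2 fold changes of the 2 comparisons had a Pearson correlation of -0.771 and a Spearman correlation of -0.783. Genes are not independent replicates, and the shared bleomycin libraries alone gave a median Pearson correlation of -0.175 in simulated data with no effect of the compound. The covariance was -0.27 against -0.0293 in those simulations, a difference of -0.241. With different bleomycin libraries in each comparison the median correlation was -0.601 (-0.66 to -0.404 over 20 splits) and the median covariance was -0.229. The 3142 genes called in both with opposite directions compare with a median of 0 in the simulated data of the same design, where the highest was 1. Genes were drawn independently in those data, which therefore lack the spread between libraries that genes share. Other assignments of the real bleomycin and treated libraries to their groups gave at most 99 such genes. With different bleomycin libraries in each comparison the number was 1251.5 (263 to 1888), for which no simulation was run.

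The bleomycin score, computed on genes chosen without the scored control or bleomycin library, was -1.86 ± 0.296 in controls (SD, n = 6), 1.13 ± 0.679 with bleomycin (SD, n = 5) and -0.629 ± 0.444 in treated lungs (SD, n = 6). The score was lower in treated than in bleomycin lungs by a difference of -1.76 and higher than in controls by 1.23. Each difference had an exact permutation p of 0.00216, and the ranges of the 3 groups did not overlap. Control libraries were scored with other signatures than treated libraries, so their scores may differ for that reason too. The p for treated against control carries this limit, and the simulated data tested the score only for treated against bleomycin.

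**Figure D3:**
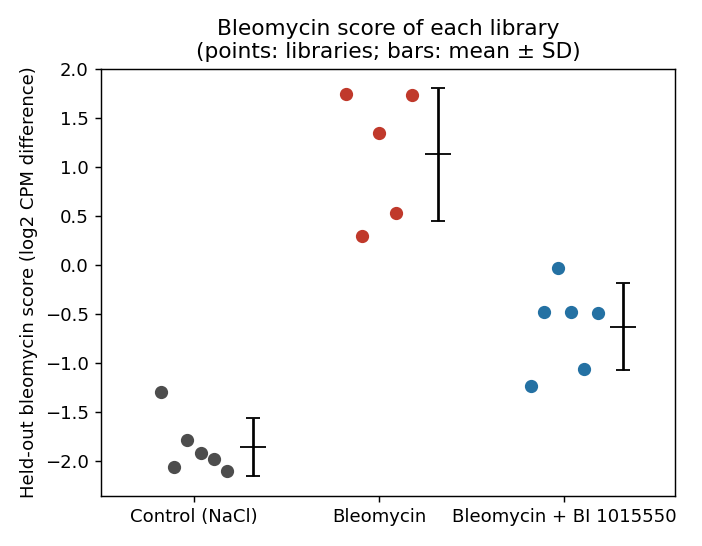
Held-out bleomycin score (difference in mean log2 CPM) of each library by group; points are libraries and bars the mean ± SD. All treated libraries (-1.24 to -0.0243) lie below the bleomycin libraries (0.301 to 1.75) and above the controls (-2.11 to -1.3).

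The third comparison asks what still differed from control in treated lungs. Treated lungs differed from controls in 1259 genes (8.39%), with 588 higher and 671 lower. Of these, 939 (74.6%) had changed with bleomycin in the same direction, 6 (0.477%) in the opposite direction, and 314 (24.9%) had not been called with bleomycin. The 939 genes comprised 446 (14.7%) of those that rose with bleomycin and 493 (18.2%) of those that fell. Independent lists would share 119 and 121. Both comparisons use the same control libraries, which makes their fold changes agree even without a bleomycin change left, and independent lists leave this out. A treated group equal to control, simulated 10 times with the control libraries shared, gave a median of 0 such genes (0 to 0). Genes were drawn independently there, so the spread between libraries that genes share is left out. These counts were not repeated with different control libraries in each comparison. ENSRNOG00000011824 remained 38.1-fold above control (log2 fold change 5.25, SE 0.361, edgeR adjusted p = 4.03e-07), and ENSRNOG00000019584 8.73-fold below it (log2 fold change -3.13, SE 0.536, edgeR adjusted p = 0.00218), with a log2 fold change of -3.99 without treated libraries 13 and 17.

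ENSRNOG00000032871 differed from control by a log2 fold change of 0.134 (SE 0.516, edgeR adjusted p = 0.912). The sign of this difference was not fixed, as it was -0.49 without treated library 13, -1.01 without treated libraries 13 and 17, -0.016 without control library 3 and -0.54 with limma voom, none past the threshold. ENSRNOG00000006151 had a log2 fold change of 5.34 against control (SE 1.64, edgeR adjusted p = 0.051), which passed the threshold with DESeq2 (adjusted p = 0.000709), with 1 surrogate variable (0.018) and without treated library 14 (0.0478) or 16 (0.0405). It was 3.83 with limma voom (adjusted p = 0.163) and 4.39 without treated library 15 (0.132), and the adjusted p was 0.108 without treated libraries 13 and 17. The count of 1259 genes was 794 without control library 2, 825 without control library 3 and 821 without treated library 15, but 2546 with limma voom. The 939 genes became 613, 625 and 621 without the same libraries, and 1921 with limma voom.

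Genes chosen as higher with bleomycin in one part of the libraries had, in the other part, a median log2 difference from control of 0.99 with bleomycin and 0.342 in treated lungs, so that 33.7% of the change was left (8.06% to 47.5% over 40 splits). For genes chosen as lower the values were -0.869 and -0.328, with 37.5% left (11.4% to 60.8%). The share left was 26.2% for genes that rose by under 2-fold, 35.3% from 2 to 4-fold and 45.9% over 4-fold. For genes that fell it was 35.1%, 37.5% and 48%. It was larger for genes over 4-fold than for genes under 2-fold in 35 of 36 splits for those that rose and in 36 of 36 for those that fell, a comparison chosen after the shares were seen. The splits reuse the same libraries, so these counts are not a test.

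**Figure D4:**
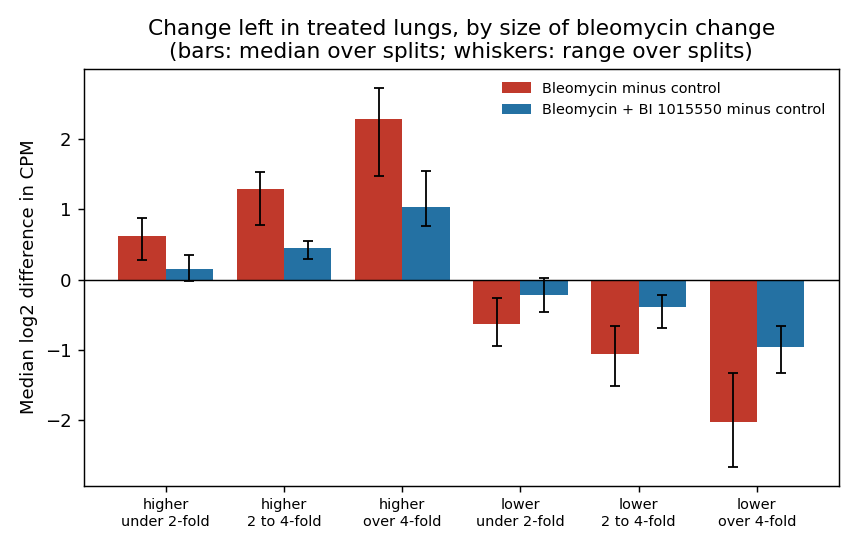
Median log2 difference in CPM from control for genes grouped by direction and size of their bleomycin change, in bleomycin lungs (red) and treated lungs (blue); genes were chosen on one part of the libraries and measured in the other, bars are medians over splits and whiskers the range. Genes that rose over 4-fold went from 2.28 with bleomycin to 1.03 in treated lungs, and genes that fell over 4-fold from -2.03 to -0.954.

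A set of 160 genes differed in treated lungs from both other groups in the same direction and was not called with bleomycin. Of these, 73 were higher, by a median log2 fold change of 0.876 against bleomycin and 1.11 against control, and 87 were lower, by -0.459 and -0.439. The count depended on single libraries. It was 105 without control library 2, 85 without treated library 13, 101 without treated library 15, 70 without treated library 17, and 38 without treated libraries 13 and 17 together. Such genes are described below as called only in treated lungs. A gene not called with bleomycin may still have changed, since the test recovered 43% of simulated 1.5-fold changes in that comparison. Those simulations changed 200 genes, while 5738 were called with bleomycin in the data. The adjustment of p was stricter in the simulations for that reason, so 43% may understate the recovery in the data.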

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

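Among 30 groups of library values examined, 2 held a library far from the rest of its group. For normally distributed values, chance alone gives such a library in about 1 in 20 groups. Both were CPM values of named genes, which were picked for large fold changes in these same libraries and need not be normally distributed. That rate may therefore not hold for them. ENSRNOG00000006151 reached 106 CPM in bleomycin library 7, while the other bleomycin libraries lay between 0.467 and 19 CPM, a gap of 0.825 of the range of the group. ENSRNOG00000019584 reached 36.6 CPM in control library 1, while the other controls lay between 5.6 and 13.5 CPM, a gap of 0.744 of the range of the group, both above the limit of Dixon's test for groups of their size. No explanation was tested for either value.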

How the results depend on the processing

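No named gene's difference past the threshold, and neither the score nor the correlation, changed sign under the alternatives run for it. Among differences of named genes that were not past it, ENSRNOG00000006151 (treated against bleomycin) turned from -2.15 to 0.0047 without bleomycin library 7, and ENSRNOG00000032871 (treated against control) turned from 0.134 to -0.54 with limma voom, -0.49 without treated library 13, -1.01 without treated libraries 13 and 17, and -0.016 without control library 3. Under upper quartile scaling 2793 of 5685 genes changed by bleomycin were higher, so that lower ones became the larger part. Alternatives of the gene lists, of the phosphodiesterase genes and of genes named by symbol were not run, since the IDs had no names. No paired analysis was possible because the groups share no replicate numbers. Thinning, leaving out treated libraries 13 and 17, and leaving out 3 libraries high on the axis within groups were chosen after seeing the data.

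Under the other scalings, filters, tools and surrogate variable, bleomycin against control gave 5448 to 6991 genes and treated against bleomycin 3593 to 4900. Fits of only the 2 groups compared gave 4939, 3888 and 1573 genes in the 3 comparisons. The main fit shares 1 estimate of the spread, but the groups were not equally spread. On the first principal component the SD was 4.37 in controls, 17 with bleomycin and 8.07 in treated lungs. The main counts, and the contrast between them, carry that limit. DESeq2 gave 243 genes called only in treated lungs. Without a filter on low counts, the correlation of fold changes was -0.6371 with DESeq2, which was run without that filter, and -0.6155 with edgeR. With limma voom, 2546 genes differed between treated and control lungs, and 1921 of them had changed alike with bleomycin. The causes were not tested. An adjusted p below 0.01 left 3512, 1812 and 425 genes in the 3 comparisons, and a fold of at least 2 left 1360, 652 and 380, by construction. Without treated libraries 13 and 17, 1929 genes differed from bleomycin, 1684 had moved back and 38 were called only in treated lungs. The share of the treated change off the bleomycin line was then 33.4%. These libraries lay nearest the controls on the first component and farthest out on the second, and fewer treated libraries were left. Falls had to follow from that choice, and whether anything else added to them was not tested. Without the 3 libraries high on the axis within groups, the comparisons gave 6195, 4611 and 1495 genes, with 3784 moved back.

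Leaving out each library in turn gave 4894 to 6359 genes for bleomycin against control, 3126 to 4427 for treated against bleomycin and 794 to 1216 for treated against control. Genes moved back ran from 2388 to 3645, genes still changed from 613 to 1074, and genes called only in treated lungs from 70 to 201. The score difference ran from -1.939 to -1.638, with an exact permutation p of at most 0.00952. Thinned to equal depth, the comparisons gave 5658, 4070 and 1211 genes. The median SE for bleomycin against control was 0.37 below 1 CPM, and how much of it came from depth was not tested.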

Other observations

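The measures of direction used here, and the test without treated libraries 13 and 17, were chosen after the principal components had been seen. Treated lungs kept 41% ± 5.58 (jackknife SE) of the bleomycin change along its own direction, and 49.4% of their squared distance from control lay off that direction. A bleomycin response scaled down by the same factor in log2 CPM for every gene has no such part. The bounds of 2 SE were 21.7% and 77.2%, so a response of that kind does not account for all of the treated change. A response scaled on the count scale, or by an amount that differs between genes, can leave the bleomycin direction and was not tested. With every library thinned to equal depth the share was 49.4%, and with the largest axis of variation within groups removed it was 53.3%, which argues against both as the cause. Without treated libraries 13 and 17 it was 33.4% (20.1% to 46.7%), but these libraries were picked for lying farthest out on the second component, so a fall had to follow, and how much rests on them stays open. No biological explanation was tested, since lungs given the compound without bleomycin were not analysed here, and an unrecorded batch or handling difference was not tested either.

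In simulated data, a treated group was placed on the bleomycin line, with the measured share of the log2 change left for every gene. It gave a median of 1.5 genes (0 to 4) called only in treated lungs, against 160 observed. It gave 1995 genes moved back (1936 to 2031) against 3142, and 603 genes still changed (564 to 699) against 939. Leaving out any 1 library gave 2388 to 3645 genes moved back and 70 to 201 called only in treated lungs, above the simulated ranges. It gave 613 to 1074 genes still changed. The genes still changed were within the simulated range without control library 2 (613), control library 3 (625), control library 6 (673) or treated library 15 (621), and above it without any other single library. Without treated libraries 13 and 17, which lay nearest the controls on the first principal component, the genes moved back were 1684, below the simulated range. The genes called only in treated lungs were 38, above their simulated range. The simulations had all 17 libraries, so none of these comparisons is between equal numbers of libraries. Genes were also drawn independently, so the simulated ranges leave out the spread between libraries that genes share.

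Libraries also differed along 1 axis within groups, which held 21.3% of the variance within groups. Library depth would have to share most of its variance with this axis to be its source, and had a Pearson correlation of -0.0123 over 17 libraries centred by group (permutation p = 0.964; Spearman 0.0956, p = 0.731; 0.018 without the 2 farthest libraries) with limits of -0.521 and 0.503, which argues against it. The share of counts in the 10 top genes had a correlation of 0.45 (permutation p = 0.128, adjusted p = 0.256 over 2 relations; Spearman 0.534, p = 0.0545; 0.185 without the 2 farthest libraries), with limits of -0.0811 and 0.782, so 17 libraries are too few to decide on it. No biological explanation was tested.

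Each of 4 counts was the highest among 100 splits of the libraries and was reached in 1 of them, the real one. This argues against chance assignment of libraries to groups. Each comparison had 462 possible splits, and those not drawn were not run. Bleomycin against control gave 5738 genes against at most 2503 in another split, treated against bleomycin 4163 against 2295, genes moved back 3142 against 99, and treated against control 1259 against 2.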
